A study of Canis lupus familiaris with 12 samples.

How the data were processed

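Gene expression was measured on 12 one-colour Affymetrix oligonucleotide arrays for the dog, each hybridised with labelled RNA of Madin-Darby canine kidney (MDCK) II tet-off cells, an established line of dog kidney tubule epithelium. Per the labels' protocols, cells were released from type I collagen gels with collagenase on day 8, and the RNA of 4 separate samples was pooled for each array. The labels call the arrays of a group biological replicates and say nothing of how the pools were drawn, so p-values measure the spread between these pools, which leaves out the spread between single cultures.

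The deposited values are 1 intensity per probe set and array on a linear scale, over 43035 probe sets. GCRMA, a background correction and summary method for Affymetrix arrays, is named in the submitters' processing notes without a version. The background model, the probe set definitions and any later scaling are not given in the sources used here. The columns had nearly the same distribution but were not identical after sorting. The values were not normalized further, and log2(intensity + 1) was used throughout, so a fold change is on that scale and understates the change of dim genes. Depth has no meaning for arrays, and the number of arrays limits the precision.

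The 111 Affymetrix control probe sets were left out of the tests, which left 42924. A filter fixed beforehand, a log2 value above 4 on at least 6 of the 12 arrays, had been written for either scale and removed no probe set here, so it was void. Genes were named from the platform annotation given with the values. Of the tested probe sets, 29254 named 1 gene, 439 named several and 13231 named none, and only those with 1 gene were used for genes. Gene identifiers of 27680 probe sets were found in the RefSeq genes of assembly UU_Cfam_GSD_1.0, which changed 0 symbols and was used for names alone, so no coordinates are given. Where several probe sets named a gene, the one with the highest mean over all 12 arrays stood for it, which gave 15115 genes. Probe sets with the suffix _s_at or _x_at can hybridise with several members of a family, so values of genes measured by such a probe set, among them CCL2, CCL7 and DLA-DQB1, are uncertain as to which member they measure.

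Arrays were grouped as 2D or 3D by the labels. The comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term, a two-sided moderated test and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. Fold changes are given with their standard error (SE), and the number of arrays is 6 per group throughout. Gene lists fixed beforehand were tested with limma's camera at a preset correlation of 0.01. Adjustment was over all 33 such lists that had at least 5 measured genes. They were tested again with a correlation estimated for each list and with fry, which asks whether a list moves on its own. Lists chosen later were adjusted apart from these. Quality measures of single values were compared with exact two-sided permutation tests over all 924 assignments of the arrays. The level of 59 control probe sets for bacterial and tag sequences, which match no dog gene, served as a background. Their 95th percentile was 5.71 on the log2 scale, averaged over arrays. Where a gene lay at or below that percentile of each array on every array of a group, the change is given as a bound against that level. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

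The design, the lists, the processing alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 12 genes raised most and the 12 lowered most among those with an adjusted p under 0.05 and no overlap between the 6 and 6 values, without placeholder symbols. It also names up to 4 members of each described list with the largest change among those that passed, or the members with the highest mean, up to 2, where fewer than 2 passed, and genes fixed by name: CDH1, TJP1, OCLN, PODXL, EXOC5, IFT88, PKD1, PKD2, MKI67, VIM and LAMA5, with 1 more that is not reported here. MKI67 was not measured by a probe set naming 1 gene and is not analysed here. The alternatives were no filter, a stricter filter of a log2 value above 6, quantile normalization, centring each array on its median, a variance prior with trend and robust fitting, array weights, the replicate number as a block, leaving out each array, a pseudocount of 16, a minimum change of 2-fold, and the mean over the probe sets of a gene. A covariate for the RNA control ratio and the removal of both arrays farthest out on the second principal component were added after the data were seen.

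The whole calculation was tested on simulated values for the same 42924 probe sets and 6 against 6 arrays. Of 50 planted changes of each size, 30% were recovered at a log2 change of 0.25, 88% at 0.5 and 100% at 1 and at 2. Of 187 calls, 9 were false, and the 1 planted list was called with 0 other lists. The simulated noise was drawn independently for each probe set, so it held no correlation between genes. The list result therefore does not test camera where the genes of a list vary together.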

Results

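Expression was compared between MDCK cells grown as flat sheets in 2-dimensional type I collagen culture (2D, 6 arrays) and MDCK cells grown as multicellular cysts in 3-dimensional type I collagen culture (3D, 6 arrays). The question was how expression in 3D differs from that in 2D, the control condition. Median intensity per array lay between 89.9 and 93.7, and the upper quartile lay between 320.1 and 342 in 2D and between 339 and 368 in 3D. The first principal component held 66.0% of the variance and separated the groups, and the second held 9.49%. The lowest correlation between arrays of a group, across probe sets, was 0.993, and the highest between groups was 0.988. No columns were identical.

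The genes raised most in 3D included CCL2, CCL7, DLA-DQA1 and ACTA2. CCL2, a chemokine that attracts monocytes, rose by a log2 fold change of 6.49 (SE 0.08), from 6.12 ± 0.19 in 2D to 12.61 ± 0.14 in 3D (SD, n = 6 arrays each; limma adjusted p = 2.72e-17). The related chemokine CCL7 rose by 5.59 (SE 0.13, limma adjusted p = 2.70e-14). DLA-DQA1, a chain of the dog class II antigen-presenting complex, lay at background in 2D and rose at least 30.8-fold, and ACTA2, smooth muscle actin, rose at least 20.9-fold. Among the named genes the largest fall was that of PDZK1, a scaffold of apical transporters, from 12.20 ± 0.15 to 9.43 ± 0.24 (log2 fold change -2.77, SE 0.10, limma adjusted p = 5.91e-12).

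The other genes that rose most were TAGLN, an actin-binding protein of contractile cells, by 4.18, DLA-DRA by 4.09, IL13RA2, a receptor that binds interleukin 13, by 3.87, and PI3, an elastase inhibitor, by 3.85. MMP13, a collagenase, rose by 3.58, as did S100A2, while SERPINE2, a protease inhibitor, rose by 3.40 and ANKRD1 by 3.33. Among the genes lowered most, ARHGAP24 fell by 1.97, ROPN1L by 1.90, the transporter SLC16A12 by 1.89, NTN4, a netrin, by 1.85 and TSPAN1 by 1.81. PTGER4, a prostaglandin E2 receptor, and RASL11A fell by 1.72 each, and DHDH fell by 1.71. MPC1, a subunit of the mitochondrial pyruvate carrier, fell by 1.48, ARHGAP18 by 1.39 and SCUBE3 by 1.35. These 24 genes were chosen among those whose 6 and 6 values did not overlap, and the plot of the genes changed most gives their values. Such separation was found for 3423 genes, and chance alone gives it for 0.216% of genes.

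**Figure D1:**
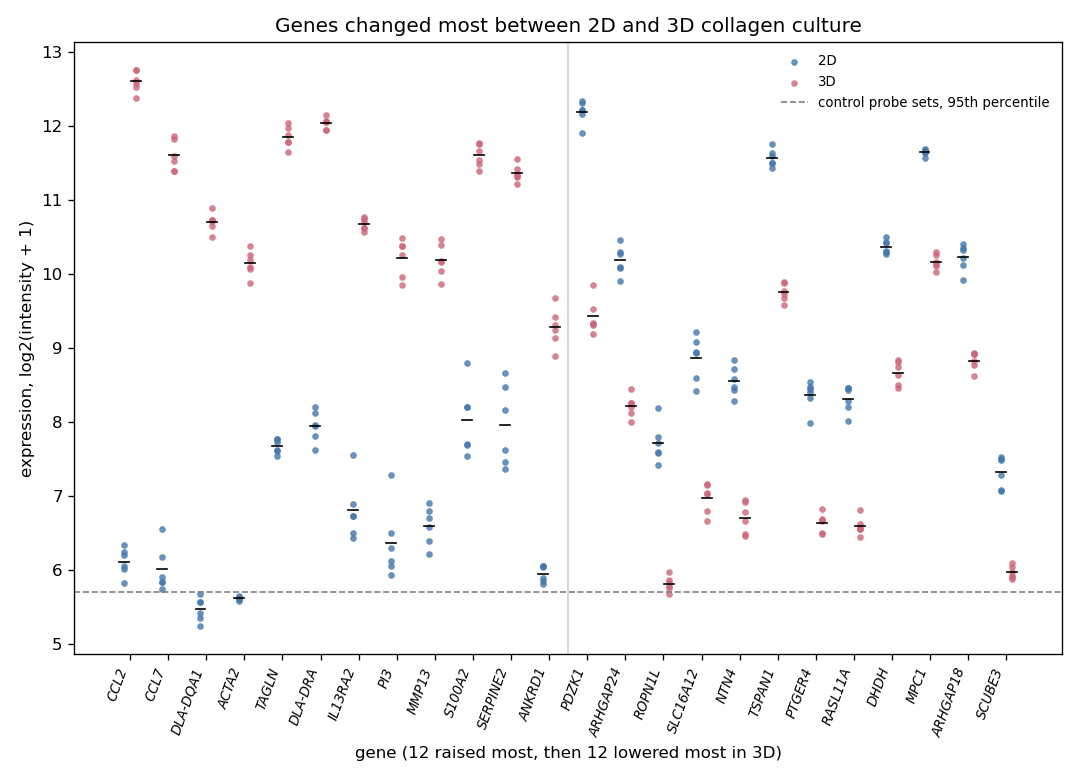
Expression of the 12 genes raised most and the 12 lowered most in 3D, as log2(intensity + 1) on the vertical axis. Each point is 1 array (6 of 2D, 6 of 3D), short bars are group means, and the dashed line is the 95th percentile of control probe sets at 5.71; DLA-DQA1 and ACTA2 lie at that level in 2D.

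Of 42924 probe sets, 7171 rose and 9437 fell, and of 15115 genes, 2988 rose and 3465 fell (limma, adjusted p under 0.05). The changes were uneven in size: 280 of the raised genes and 41 of the lowered genes changed at least 2-fold, and the median log2 fold change was 0.35 among raised and -0.23 among lowered genes. The 11819 probe sets at or below the control level held 417 of the raised and 1947 of the lowered probe sets. The ratio of 5-prime to 3-prime signal of the actin and GAPDH control probe sets, a sign of RNA integrity, also differed with culture, with a mean log2 of -0.92 ± 0.14 in 2D and -0.54 ± 0.17 in 3D (SD, n = 6 each, exact permutation p = 0.00866), as the plot of the ratio per array shows. This difference lay alongside every gene group described here. It was uneven between the control genes. An actin pair tested singly had a ratio of 1.07 ± 0.15 in 2D and 1.45 ± 0.20 in 3D (exact permutation p = 0.00866). A GAPDH pair had 0.91 ± 0.04 and 0.95 ± 0.05 (exact permutation p = 0.190). Whether culture changed the actin signal itself was not tested. With the mean log2 ratio as a covariate, chosen after the data were seen, 1907 genes rose and 1259 fell.

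**Figure D2:**
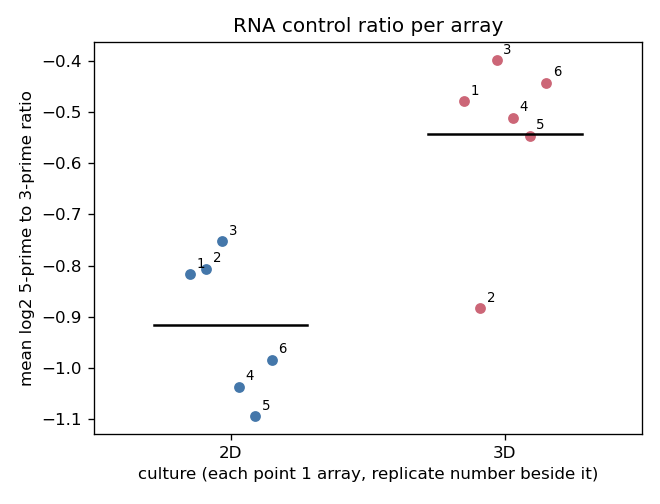
Mean log2 ratio of 5-prime to 3-prime signal of the actin and GAPDH control probe sets on each array, by culture, with the replicate number beside each point and bars at the group means of -0.92 (2D) and -0.54 (3D). The array of 3D replicate 2, at -0.88, lies within the range of the 2D arrays.

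Inflammatory genes rose as a group in 3D. Of 25 measured NF-kB and inflammatory genes, 17 rose, 1 fell and 7 did not pass (17 and 1 adjusted over the list alone; camera adjusted p = 3.79e-11). Besides CCL2, PTGS2, the inducible cyclooxygenase, rose by 3.03 (SE 0.15) and CSF2, a myeloid growth factor, by 2.86 (SE 0.08), while the neutrophil chemokine CXCL8 lay at background in 2D and rose at least 3.72-fold. Of 26 interferon-stimulated genes, 19 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 1.62e-09). The nuclease ISG20 rose by 2.37, the immunoproteasome subunit PSMB9 by 2.01, OAS1 by 1.35 and the peptide transporter TAP1 by 1.25. The probe sets of OAS1 disagreed, with 4 raised and 1 lowered.

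Genes of the cell cycle rose together. In the mitosis list 21 of 24 genes rose and 0 fell (22 and 2 adjusted over the list alone and also at an unadjusted limma p under 0.05), with a mean log2 fold change of 1.35. The list was called by camera (adjusted p = 3.91e-17) but not with its correlation estimated (adjusted p = 0.0819 with an estimated correlation). NUSAP1, a spindle protein, rose by 2.01 (SE 0.14), the topoisomerase TOP2A by 1.91, the checkpoint kinase BUB1B by 1.89 and the kinetochore gene NUF2 by 1.89. Of 32 DNA replication genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone and at an unadjusted limma p; camera adjusted p = 2.98e-17). Thymidine kinase TK1 rose by 1.79, the licensing factor CDC6 by 1.26 and the helicase subunits MCM3 by 1.20 and MCM5 by 1.18.

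Signalling lists tied to growth gave mixed results. Of 21 genes of ERK pathway feedback, 13 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 1.84e-06). Cyclin D1, CCND1, rose by 1.89, the transcription factor ETV1 by 1.85, the phosphatase DUSP6 by 1.72 and IER3 by 1.53. Of 24 p53 and apoptosis genes, 11 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.0460, and adjusted p = 0.107 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A rose by 1.79, PLK2 by 1.60, BAK1 by 0.99 and CASP8 by 0.77. That call ended with quantile normalization (adjusted p = 0.0919), with centring on the median (0.0502), with the stricter filter (0.0702), with the RNA ratio as a covariate (0.0665) and without any 1 of 4 arrays (0.0505 to 0.0604: 2D replicate 1 and 3D replicates 1, 3 and 4). The Wnt list (5 rose and 5 fell of 28, the same adjusted over the list alone) did not pass (camera adjusted p = 0.877). The list of growth factors and receptors did not either (7 rose and 8 fell of 35, the same adjusted over the list alone; camera adjusted p = 0.877). Their medians of -0.06 and -0.04 and means of 0.07 and 0.05 differed in sign. Within them MYC rose by 0.68, the Wnt receptor FZD2 by 0.66, and WNT7A by 0.54. IGFBP6 rose by 1.82, the ErbB ligand NRG1 by 1.74 and IGF2 by 0.87, and the receptor FGFR2 fell by 1.22.

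Contractile, adhesion and protease genes were higher in 3D. Of 26 actomyosin genes, 17 rose and 3 fell (17 and 3 adjusted over the list alone; camera adjusted p = 1.95e-07). After ACTA2 and TAGLN, the myosin light chain MYL9 rose by 2.16 and TAGLN2 by 1.07. Of 29 integrin and focal adhesion genes, 18 rose and 1 fell (20 and 2 adjusted over the list alone; camera adjusted p = 6.09e-07, and adjusted p = 0.145 with an estimated correlation). The actin crosslinker ACTN1 rose by 1.59, the laminin-binding integrin ITGA3 by 1.06, vinculin, VCL, by 1.03 and filamin A, FLNA, by 1.00. Among 24 matrix proteases and inhibitors, 12 rose and 1 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000143). Beyond MMP13 and SERPINE2, the gelatinase MMP9 rose by 3.24 and the inhibitor TIMP3 by 2.27.

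Mesenchymal, TGF-beta, YAP/TAZ and matrix genes were tested as separate lists. Of 21 mesenchymal genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0140, and adjusted p = 0.119 with an estimated correlation). S100A4 rose by 2.51, the repressor SNAI2 by 1.64, the matrix protein TGFBI by 1.37, and INHBA, an activin subunit at background in 2D, at least 4.57-fold. VIM, the intermediate filament vimentin, rose by 0.47 (SE 0.05). Of 24 TGF-beta and BMP targets, 11 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.000790). The BMP target genes ID3 and ID1 rose by 1.83 and 1.80. The YAP/TAZ targets had 6 raised and 4 lowered of 18 (7 and 5 adjusted over the list alone; camera adjusted p = 0.236), with a median of -0.05 against a mean of 0.34. After ANKRD1, a gene of this list named above, tissue factor, F3, rose by 2.47 and CCN1 by 0.78, while CRIM1 fell by 0.78. Of 29 matrix and basement membrane genes, 10 rose and 0 fell (10 and 2 adjusted over the list alone, 4 lowered at an unadjusted limma p; camera adjusted p = 0.0880, but 0.0315 with quantile normalization and 0.0338 with the stricter filter). The laminin chains LAMA3 and LAMC1 rose by 1.88 and 0.78, fibronectin, FN1, by 1.23 and FBLN1 by 0.94. LAMA5 had a log2 fold change of 0.005 (SE 0.06, limma adjusted p = 0.956).

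Glycolytic genes rose throughout the list. All 18 measured glycolysis genes rose (18 adjusted over the list alone, and 16 with the RNA ratio as a covariate; camera adjusted p = 1.75e-13, and adjusted p = 0.0515 with an estimated correlation), with a mean of 0.72. The lactate exporter SLC16A3 rose by 1.68, phosphoglycerate kinase PGK1 by 1.29, PFKP by 1.26 and aldolase ALDOA by 0.94. Of 25 hypoxia-inducible genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.000133, and adjusted p = 0.145 with an estimated correlation). The glucose transporter SLC2A1 rose by 1.43, PFKFB3 by 1.38 and ERO1A by 1.18, and DDIT4, at background in 2D, rose at least 2.82-fold. Oxidative phosphorylation genes did not pass as a list (2 rose and 8 fell of 34, 1 and 8 adjusted over the list alone; camera adjusted p = 0.199), and the list passed with quantile normalization (adjusted p = 0.00606). NDUFV1 fell by 0.24, NDUFA4 by 0.20 and SDHC by 0.18, and NDUFV2 rose by 0.19.

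Other metabolic and stress lists shifted little. Of 20 cholesterol synthesis genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0285, and adjusted p = 0.228 with an estimated correlation). FDPS rose by 0.58, DHCR7 by 0.51 and CYP51A1 by 0.36, and PMVK fell by 0.38. Of 24 unfolded protein response genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0362, and adjusted p = 0.423 with an estimated correlation). DNAJC3 rose by 0.80, although 1 of its 4 probe sets fell, the asparagine synthetase ASNS by 0.59, and PDIA4 and CHAC1 by 0.44 each. Both calls ended with quantile normalization (adjusted p = 0.186 and 0.227), the stricter filter (0.114 and 0.146) and the RNA ratio as a covariate (0.138 and 0.234), and that of the unfolded protein response also without 3D replicate 3 (0.0536). Fatty acid oxidation genes went both ways (6 rose and 8 fell of 24, 6 and 10 adjusted over the list alone; camera adjusted p = 0.778). PDK4 rose by 0.89 and CPT1A by 0.74, and CPT2 fell by 0.59 and ACADS by 0.40. Lysosomal genes did too (9 rose and 10 fell of 28, 10 and 10 adjusted over the list alone; camera adjusted p = 0.547). The cathepsins CTSH and CTSD rose by 0.98 and 0.75 and NPC1 by 0.51, and MCOLN1 fell by 0.55.

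Genes of the primary cilium, a sensory organelle of epithelial cells, were lower in 3D. Of 37 measured members, 22 fell and 0 rose (23 and 1 adjusted over the list alone and at an unadjusted limma p), with a mean log2 fold change of -0.22. Camera called the list (adjusted p = 2.12e-05), but not with its correlation estimated (adjusted p = 0.230 with an estimated correlation). TCTN2 fell by 0.62 (SE 0.06), BBS5 by 0.52, IFT88, a carrier of intraflagellar transport, by 0.51 and TMEM67 by 0.50. The polycystin genes PKD1 (log2 fold change -0.002, SE 0.09, limma adjusted p = 0.986) and PKD2 (-0.19, SE 0.09, limma adjusted p = 0.106) did not pass. PKD2 passed with quantile normalization (-0.29, limma adjusted p = 0.00728), with the RNA ratio as a covariate (-0.53, limma adjusted p = 0.000982), without 2D replicate 6 (-0.24, limma adjusted p = 0.0424) and without both 2D replicate 6 and 3D replicate 2 (-0.16, limma adjusted p = 0.0384). Without 3D replicate 2 alone it had a log2 fold change of -0.11 (limma adjusted p = 0.203).

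Kidney transport genes and ribosomal protein genes were slightly lower. Of 39 transporters and channels, 17 fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p = 0.0460, and adjusted p = 0.423 with an estimated correlation). FXYD2, a subunit of the sodium pump, fell by 0.76 and the endocytic receptor CUBN by 0.34, while ATP6V1B1 rose by 0.71 and ATP1B1 by 0.41. The call ended with quantile normalization (adjusted p = 0.137), with the RNA ratio as a covariate (0.585) and without any 1 of 7 arrays (0.0536 to 0.0601: 2D replicates 1, 5 and 6 and 3D replicates 1, 3, 4 and 6). Of 32 ribosomal protein genes, 22 fell and 1 rose (24 and 1 adjusted over the list alone; camera adjusted p = 3.27e-05, and adjusted p = 0.460 with an estimated correlation). RPL12 fell by 0.39, RPS28 by 0.30, and RPL22 and RPL13 by 0.29 each. The call of RPL22 ended with centring on the median (limma adjusted p = 0.0578) and without any 1 of 5 arrays (0.0534 to 0.0649: 2D replicates 2, 3, 4 and 5 and 3D replicate 1). Without 3D replicate 2 RPL22 had a log2 fold change of -0.19 (limma adjusted p = 0.0217), and with the RNA ratio as a covariate -0.62 (limma adjusted p = 0.00416). Kidney transcription factors went both ways (6 rose and 8 fell of 28, the same adjusted over the list alone; camera adjusted p = 0.778). KLF4 rose by 1.67, TFAP2B by 0.62 and SOX9 by 0.47, and IRX3 fell by 0.42. The median of these genes was -0.05 and their mean 0.03.

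The lists of junction, polarity and exocyst genes did not pass camera, while fry, which does not compare a list with other genes, called them higher (adjusted p = 0.000218, 0.000572 and 0.000329). The junction list had 13 raised and 7 lowered of 30 genes (13 and 7 adjusted over the list alone; camera adjusted p = 0.135). The desmosomal genes DSC2 and DSP rose by 1.23 and 0.77, claudin 1, CLDN1, by 1.07 and E-cadherin, CDH1, by 1.02 (SE 0.20, limma adjusted p = 0.000688), while occludin, OCLN, fell by 0.24 and TJP1 by 0.19. With the RNA ratio as a covariate CDH1 had a log2 fold change of 0.15 (SE 0.15, limma adjusted p = 0.576), and TJP1 of -0.16 (SE 0.07, limma adjusted p = 0.160), and the call of TJP1 ended with the mean of its probe sets (-0.06). Of 24 polarity genes, 9 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.135). ECT2 rose by 1.89, GPSM2 by 0.64, ANXA2 by 0.57 and LLGL1 by 0.44. The median was -0.02 and the mean 0.14. PODXL, an apical sialomucin, did not pass (log2 fold change -0.12, SE 0.06, limma adjusted p = 0.0868). PODXL passed with array weights (-0.15, limma adjusted p = 0.0198), without 2D replicate 6 (0.0464), without 3D replicate 2 (0.0224) and without both of these arrays (-0.18, limma adjusted p = 0.00859), and the polarity list passed with the mean of the probe sets of a gene (camera adjusted p = 0.0483). Of 25 genes of the exocyst and of polarized traffic, 9 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 0.0880, and 0.0309 without 3D replicate 2). The small GTPases RALA rose by 1.69, RAB27A by 0.98 and ARF6 by 0.66, EXOC6B by 0.65 and EXOC5 by 0.35 (SE 0.10, limma adjusted p = 0.0137). The direction of EXOC5 did not hold with the RNA ratio as a covariate (log2 fold change -0.007, SE 0.12, limma adjusted p = 0.978).

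Markers of other cell types and of handling stress were also measured. Fibroblast markers (1 rose and 3 fell of 15, the same adjusted over the list alone; camera adjusted p = 0.132, and 0.0384 with the mean of the probe sets of a gene), endothelial markers (1 rose and 2 fell of 11, the same adjusted over the list alone; camera adjusted p = 0.293) and leukocyte markers (1 rose and 6 fell of 14, the same adjusted over the list alone; camera adjusted p = 0.291) did not pass. COL5A1 fell by 0.52, COL1A1 by 0.21, ESAM by 0.24, ITGAM by 0.26, CD4 by 0.22 and CD3E by 0.19, DCN fell to background, at least 1.06-fold, and PECAM1 lay at background in both groups, and COL5A2 rose by 0.32, EGFL7 by 0.24 and CD14 by 0.43. The call of ITGAM ended without any 1 of 4 arrays (limma adjusted p = 0.0507 to 0.0649: 2D replicate 1 and 3D replicates 3, 4 and 5). That of CD4 ended without any 1 of 8 arrays (0.0581 to 0.0866: 2D replicates 1, 2, 4 and 6 and 3D replicates 1, 3, 4 and 6), with centring on the median (0.0569) and with the mean of its probe sets (0.0541). The calls of COL1A1, PECAM1 and ITGAM ended with quantile normalization (limma adjusted p = 0.0740, 0.0569 and 0.0638). Immediate early and heat shock genes had 6 raised and 2 lowered of 21 (6 and 1 adjusted over the list alone; camera adjusted p = 0.182). JUNB rose by 0.98, KLF6 by 0.75 and BAG3 by 0.42, and IER2 fell by 0.52, a call that ended with the mean of its probe sets (limma adjusted p = 0.0598). With the RNA ratio as a covariate the call of EXOC5 ended, and so did those of 23 other named genes. For 12 of them the log2 fold change stayed within 1.5 times its value (shares left of 0.800 to 1.37) while the SE grew by a median factor of 1.64: NDUFA4, NDUFV2, SDHC, CUBN, IER2, COL5A2, DCN, COL1A1, EGFL7, ESAM, PECAM1 and TJP1. For the other 11 it shrank by more than that: CDH1, LAMC1 (to 0.42, SE 0.15), CCN1 (0.48, SE 0.27), WNT7A (0.35, SE 0.13), SOX9 (0.24, SE 0.09), CASP8 (0.25, SE 0.10), MCOLN1 (-0.18, SE 0.21), JUNB (0.64, SE 0.25), ITGAM (-0.15, SE 0.14), CD4 (-0.05, SE 0.12) and CD3E (-0.11, SE 0.09).

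Several probe sets named 97 of the called genes given here, and for 26 of these at least 1 probe set was not called in the direction of the gene. With the mean over its probe sets the log2 fold change of 29 named genes moved by over 1.5 times. MMP9 then had 1.01, with 1 of 3 probe sets raised, FBLN1 0.18, with 1 of 5, and MCM3 0.47, with 2 of 4. VCL had 0.49, KLF4 0.80, BAK1 0.49, ATP6V1B1 0.38, CPT1A 0.43 and PDK4 0.52, with 1 of 2 probe sets raised for each. PFKFB3 had 0.63, NUSAP1 1.12 and DNAJC3 0.48, with 3 of 4 raised, and NRG1 0.83 and LAMA3 1.13, with 2 of 3. TCTN2 had -0.33, OCLN -0.12, CD4 -0.14 and TJP1 -0.06, with 1 of 2 lowered, COL1A1 -0.10, with 1 of 3, and COL5A1 -0.27 and PECAM1 -0.13, with 3 of 4. The probe sets of CDKN1A (0.79), PGK1 (0.69), CDC6 (0.69), CXCL8 (1.73), PI3 (2.54), ROPN1L (-1.15), NDUFA4 (-0.31) and CHAC1 (0.86) were all called in 1 direction.

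In all, camera called 18 of the 33 lists, 15 higher and 3 lower in 3D, and 7 held with an estimated correlation: DNA replication (adjusted p = 0.0491 with an estimated correlation), matrix proteases, actomyosin and ERK feedback (0.0407 each), and the inflammatory, interferon and TGF-beta lists (0.0331 each). In 99 other splits of the arrays into 6 and 6, camera with the preset correlation called a median of 9 lists. Many of these splits kept part of the contrast between cultures, so this median is no chance level. Splits that swapped 3 arrays of each culture, which keep none of it, called 0 to 5 lists. Of the lists that did not pass camera, fry also called the matrix (adjusted p = 4.83e-06), YAP/TAZ (2.01e-05) and growth factor (0.0321) lists higher and the oxidative phosphorylation (0.00720), fibroblast (0.00294) and endothelial (0.00954) lists lower. The plot of gene list shifts gives the spread of each list.

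**Figure D3:**
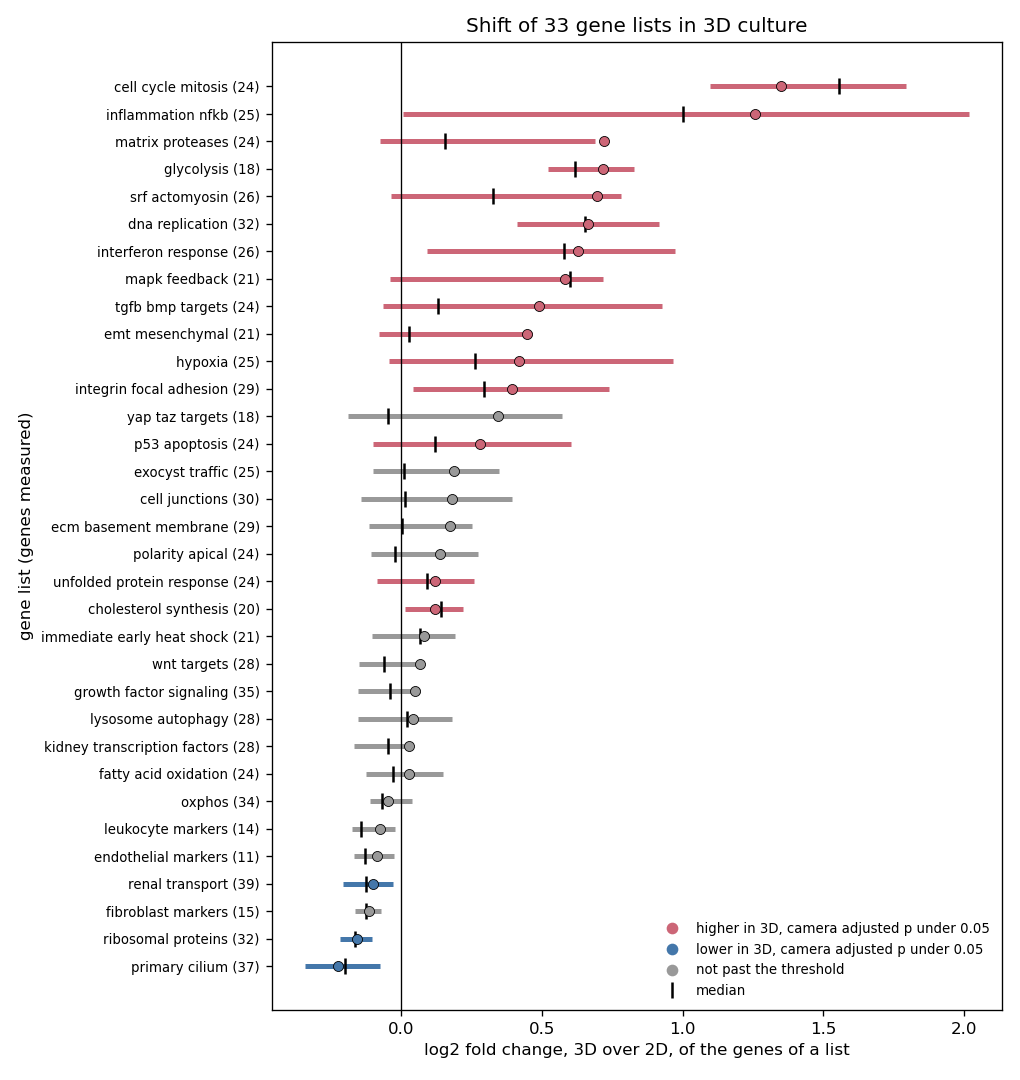
Log2 fold change in 3D over 2D of the genes of 33 lists on the horizontal axis, with the number of measured genes beside each name. Circles are means, black ticks medians and bars the quartiles over genes; colours mark the camera result, with 15 lists higher, 3 lower and the rest not past the threshold.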

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

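The tests of a lower background and of fibroblasts and leukocytes were chosen only after the results they bear on had been seen. The test of RNA integrity was written down before its result.

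Of 378 groups of 6 arrays checked, over named genes, lists and quality measures, 36 held 1 array far from the other 5, against 18.9 that chance gives at about 1 in 20. The arrays of 3D replicate 2, with 11, and of 2D replicate 6, with 7, held the most. In 3D replicate 2 the log2 level was low for CLDN1 (7.98), CDH1 (6.65, with the other 3D arrays between 7.68 and 8.13), LAMC1 (9.20), DNAJC3 (7.98), ATP6V1B1 (7.34), RPL22 (7.64) and PKD2 (8.21). The mean level of its exocyst list (9.07) and junction list (9.61) was also low, and that of its renal transport list (7.12) was high. In 2D replicate 6 the level of MYL9 was high (6.13), and those of RPL13 (13.69), COL5A2 (12.69) and VIM (13.80) were low, as were the means of the primary cilium (8.38), focal adhesion (9.37) and ribosomal protein (13.11) lists.

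In 2D replicate 2 the levels of DDIT4 (5.70) and PGK1 (12.44) and the mean of the hypoxia list (8.53) stood above those of the other 2D arrays. In 2D replicate 5 DHCR7 (7.02) and the means of the cholesterol (9.36) and kidney transcription factor (7.55) lists were high and FZD2 was low (8.39). PMVK was low in 2D replicate 3 (9.20), and PECAM1 in 2D replicate 1 (5.25). In 3D replicate 6 FN1 (12.52) and FLNA (11.94) were low and EGFL7 was high (10.74). In 3D replicate 1 CTSD (12.46) and MCOLN1 (7.32) were low. OCLN was low in 3D replicate 3 (10.28), where the mean of the mitosis list was high (8.18). In 3D replicate 5 NDUFV1 was low (11.27) and COL5A1 high (8.45).

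The control probe sets for RNA integrity, which were not among the probe sets tested, had a mean log2 5-prime to 3-prime ratio higher by 0.37 in 3D than in 2D, and that of 3D replicate 2 (-0.88) was the farthest from its group. For the 321 genes changed at least 2-fold, a difference in RNA integrity was weighed as a technical cause. With the ratio as a covariate the median share of the log2 fold change left was 0.987 (quartiles 0.929 and 1.05), and 320 of these genes kept their call and direction. These changes thus mostly did not follow the ratio among arrays of 1 culture. Except for 3D replicate 2, the ratio separated the cultures (2D -1.09 to -0.75, other 3D arrays -0.55 to -0.40). The fit leans in part on that array, so integrity is not excluded as a cause of the large changes. For called genes under 2-fold the median share left was 0.886 and the SE grew by a median factor of 1.60, and for CDH1 the log2 fold change went from 1.02 to 0.15. The cause of single lost calls was not tested. An effect of culture on the RNA itself was not tested and stays open.

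Many dim probe sets fell slightly in 3D: 1947 of 11819 were called lower, with a median log2 fold change of -0.20. A lower background on the 3D arrays as deposited is a possible explanation. Control probe sets that match no dog gene had a median change of -0.053 (SE 0.013), about 26.1% of that fall, below what a full background effect asked for and not clearly above what its absence asked for. Their 95th percentile had a change of -0.106 (exact permutation p = 0.0130) and their mean of -0.064 (exact permutation p = 0.00866). The medians of dim probe sets with 1 named gene (-0.07) and without (-0.08) lay close to that of the controls. The called probe sets were picked for falling, which keeps the question open: a background effect and small true falls cannot be told apart.

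ACTA2, TAGLN, DLA-DQA1 and DLA-DRA rose in 3D, and cells of other types were weighed as a source. The abundant fibroblast genes COL1A1, COL1A2, COL3A1 and DCN had a median log2 fold change of -0.19 (range -0.25 to -0.13). The leukocyte genes PTPRC, CORO1A, LCP1, CD52 and LYZ had a median of -0.14 (range -0.17 to 0.13). The highest mean levels in 3D were 6.52 and 6.03 for the chosen fibroblast and leukocyte genes, near the control level of 5.71. Both results argue against such cells as the source of these changes, provided these probe sets detect their genes. That was not tested. In the full marker lists, COL5A2 and CD14 rose, while 3 fibroblast and 6 leukocyte markers fell. A response of the MDCK cells to 3D culture remains a hypothesis.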

How the results depend on the processing

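The RNA ratio as a covariate and the removal of 2D replicate 6 and 3D replicate 2 were chosen only after the data were seen. Requiring a change of at least 2-fold left 621 probe sets higher and 102 lower, and 280 genes higher and 41 lower, since most changes were small. With an estimated correlation camera called 7 lists higher and 0 lower (11 and 0 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 21 higher and 6 lower. With the RNA ratio as a covariate 4303 probe sets rose and 3624 fell, and 1907 genes rose and 1259 fell, so that 60.2% of called genes were higher against 46.3% without it; 2795 of the 6453 called genes kept their call and direction. With it neither the direction nor the call of EXOC5 held (log2 fold change -0.0069, SE 0.12). It also ended the calls of 23 other named genes, 12 of which kept a log2 fold change within 1.5 times its value with an SE larger by a median factor of 1.64. Under the other settings the counts that were run stayed within 1.5 times their value, with no probe set counts for the mean over the probe sets of a gene. Leaving out each array in turn gave 6453 to 8033 probe sets higher and 7430 to 11016 lower, 2729 to 3198 genes higher and 2777 to 3942 lower, and 13 to 16 lists higher and 2 to 3 lower, with the highest gene counts without 3D replicate 2. Without both arrays that stood apart 3135 genes rose and 3870 fell. Median centring gave 3205 and 2680, quantile normalization 2621 and 3405, and the stricter filter, with 27359 probe sets, 2926 and 2758. Similar totals did not mean the same genes. Of the 6453 called genes, 5668 kept their call and direction with median centring and 5073 (78.6%) with quantile normalization. The absence of a filter moved nothing, since the planned filter removed no probe set. Of 3538 values of named genes under these settings 3481 kept their side of the threshold and direction, 48 lost the call, 8 gained it and 1, that of EXOC5, changed sign. Of 825 values of lists, 775 kept theirs, 35 lost the call and 15 gained it. The causes were not tested. The replicate numbers were not taken to pair the arrays, since the correlation of same-numbered arrays in their deviations from the group means was above 0.1 for 3 of 6 pairs only. All 6 were positive (0.0008 to 0.360), and 5 of the 12 arrays correlated best with their own number, a hint from the data that some numbers share more than a name. That hint is weak, since a pair with different numbers, 2D replicate 6 and 3D replicate 2, had a correlation of 0.274. With the replicate block 7402 probe sets rose and 9728 fell, 3055 genes rose and 3542 fell, and 15 lists were higher and 3 lower. Signal over background limits the 11819 probe sets at or below the control level, whose changes can be understated.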

Other observations

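The tests of fibroblasts and leukocytes above were chosen only after the genes changed most had been seen. So were the lists of motile cilium, class I, class II and smooth muscle genes here. The predictions for the motile cilium and class II lists were written before those lists were tested. Camera p-values of the lists here were adjusted over these lists only, without the lists fixed beforehand. That adjustment covers fewer lists, so these values cannot be compared with the adjusted p-values of the fixed lists.

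Genes of the motile cilium axoneme were lower in 3D as a group. ROPN1L, DRC1 (log2 fold change -1.33), DAW1 and AK8 (-1.10) were among the genes lowered most. DAW1 fell to background, at least 1.69-fold, and 1 of the 2 probe sets of AK8 was lowered. The hypothesis was that the other axoneme genes fall too. Of 71 such genes, leaving out those already seen, 34 fell and 3 rose (40 and 3 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 1.17e-05, and adjusted p = 0.0187 with an estimated correlation). Of these, 13 lay at background in both cultures, and the median is near that of dim probe sets called lower (-0.20). Camera compared the list with all other genes, not with equally dim ones. For its dim members a lower background cannot be told apart from a true fall. CFAP126 fell by 0.81 (1 of 2 probe sets lowered), CCDC65 by 0.73, the dynein docking gene ODAD3 by 0.62 and DNAAF1 by 0.58 (1 of 4 lowered). FOXJ1, a transcription factor in this list, lay at background in both cultures (5.23 in 2D and 5.01 in 3D). A lower axoneme program in 3D remains a hypothesis.

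Genes of antigen presentation were tested as separate lists. Of 19 class I and peptide loading genes, which include the already seen PSMB9 and TAP1, 14 rose and 0 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.14e-08, and adjusted p = 0.0185 with an estimated correlation). Without PSMB9 and TAP1, 12 of 17 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.43e-06, and adjusted p = 0.0187 with an estimated correlation). Without all 5 genes that the lists of the report hold, 11 of 14 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 1.90e-07, and adjusted p = 0.0187 with an estimated correlation). DLA-64 rose by 1.87, DLA88 by 1.33, PSMB10 by 1.14 and B2M by 0.84. For class II, DLA-DQA1, DLA-DRA, HLA-DRB1 (3.24), which carries its human symbol in the annotation, and DLA-DQB1 (2.94) were among the genes raised most. The hypothesis was that the rest of the pathway rises, so these genes were left out of the tested list, and the lists of class I and class II were not compared with each other. The 11 other class II genes did not bear that out as a list (camera adjusted p = 0.144): 5 rose and 4 fell (the same adjusted over the list alone). DLA-DMB rose by 1.36, DLA-DMA by 1.22 and CD74 by 0.74, and the transactivator CIITA fell by 0.25, with 1 of its 2 probe sets lowered. Of 10 smooth muscle genes other than those named above, 1 rose and 3 fell (camera adjusted p = 0.514). SMTN rose by 0.62 and MYH11 fell by 0.24. The 4 probe sets of MYH11 disagreed, with 1 raised and 1 lowered.

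Other splits of the 12 arrays into 6 and 6 were compared with the real one. Of 100 splits, the real one included, 1 split called as many probe sets (16608, with 9716 as the highest of the others) and 1 split as many genes (6453, against 3423). That is the smallest share that 100 splits can give. A split that mixes the cultures also moves their difference into the spread within its groups, which lowers its calls. That happens only where the groups differ. The counts of probe sets and genes therefore argue against a chance division of the arrays as their source. They do not tell culture from anything else that differed between the groups. For lists 3 splits of 100 called as many as the 18 of the real one, with 18 as the highest of the others. The other splits called a median of 9 lists, and 97 of the 99 called no gene, with up to 18 lists among these. Splits that swapped 1 or 2 arrays of each culture kept part of the real contrast and called 6 to 18 lists. Those that swapped 3 called 0 to 5. The count of lists over all splits is therefore no chance level, and nothing is drawn from that count here.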
